A study of Mus musculus with 6 samples.

How the data were processed

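The series holds 6 arrays of mouse hippocampus RNA, 1 per mouse, from 3 Dp(11)17/+ mice and 3 +/+ mice. RNA was labelled with biotin and hybridized to Affymetrix mouse expression arrays in 1 colour. The extraction protocol in the labels lists other organs and not hippocampus, and the labelling protocol speaks of pools while each sample names 1 individual. The tissue and individual of the sample records were used here. The deposited values are on the log2 scale, 1 per probe set, and were made by the authors with RMA, as the submitters' processing notes state, which corrects background, applies quantile normalization over the arrays together and summarises probes by median polish. The version of RMA is not given in the sources used here. The values were between 2.14 and 13.09, with medians of 3.74 to 3.79 and upper quartiles of 5.89 to 5.99, and were used as deposited, with no pseudocount and no further normalization. Arrays give signal and no counts, so their number limits the precision.

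From the table, 64 control probe sets were left out and 45037 probe sets tested. Of these, 34945 had 1 gene symbol, 932 several and 9160 none. A gene table of the assembly GRCm38.p6 was used for names, chromosomes and gene order, with no coordinates, because the deposited values name no genome build. Through Entrez identifiers 34741 of the 34945 probe sets were found in it and 204 were not. Gene-level results used 18193 genes, each by the probe set with the highest mean over the 6 arrays. The duplicated segment was taken as all genes from Cops3 to Rnf112 in that order, 70 in the gene table, 32 of them protein-coding, and 33 measured with 61 probe sets. Flanking genes were lists fixed by name on both sides, of which 31 were measured.

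Duplication was compared with wild type by limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend, no covariate and two-sided moderated statistics with 7.11 degrees of freedom, 3.11 of them from the prior. Benjamini-Hochberg adjustment was over the 45037 probe sets, with a threshold of 0.05. The lists of the segment and of its flanks were also adjusted over the list alone. Dosage was taken over the segment's genes with a mean log2 value of 6 or more over all 6 arrays. It was set against a copy ratio of 3 to 2, or 1.5, and tested on the mean per mouse with an exact two-sided permutation test over 20 labelings. Gene lists for pathways, cell types and neighbouring regions, 33 in all, were tested two-sided with camera at a preset correlation of 0.01, against 18160 measured genes with those of the segment left out. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without a comparison to other genes, were run beside it. Benjamini-Hochberg adjustment was over the 33 lists. The lists, the tests, the segment and the rule for naming genes were chosen before the data were examined, apart from the exceptions stated here and below. Camera and fry on the segment, its flanks and the rest of chromosome 11 as sets were not planned. They were run among all 18193 genes, with those of the segment kept in. The unadjusted threshold and the windows by gene number on chromosome 11 also differ from the plan.

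The rule named genes of the segment past the threshold, up to 15 by fold change, and always Rai1, Srebf1, Cops3, Rnf112, Flcn and Mprip. Outside the segment it named the probe sets past the threshold, or, where none pass, the 10 with 1 symbol and the smallest unadjusted p. In each list it named the 3 members with the smallest unadjusted p, and among flanking genes those past the threshold, up to 6. No gene of the segment passed over all probe sets, so the rule was applied to the adjustment over the list alone, and Usp22, Tmem11, Map2k3, Rasd1, Fam83g, Pigl, Wnt9a and the genes of chromosome 11 with p under 0.01 were named after their values were seen. A gene was reported by its probe set of the highest mean, and opposite signs between probe sets of which 1 had an unadjusted p under 0.05 were stated.

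Calls on chromosome 11 outside the segment and its flanks were compared with other chromosomes by a two-sided Fisher exact test at unadjusted p under 0.01, with 0.001 and 0.05 beside it, and changes along the chromosome were summarised in 73 windows of 20 neighbouring measured genes. Alternatives were filters on dim probe sets, quantile normalization again, centring on array medians, cyclic loess, an intensity trend with robust prior, array weights, a plain equal-variance statistic, other thresholds, other probe set choices, other floors, other list tests and each mouse left out. Added after the data were seen were duplication replicate 2 alone against wild type, a regional marker score per array as a covariate, and 30 neighbouring genes on each side as flanks. With duplication replicate 2 alone, that mouse is assumed to vary like the wild-type mice. Its p would carry no variation between duplication mice, so effect sizes alone are given for that fit. The score was the mean of the thalamic and striatal lists minus the mean of the CA1 and dentate lists.

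The fits were tested on simulated data of 45037 independent probe sets and 3 mice in each group. For the test of single probe sets, 200 with a mean log2 value of 6 or more were changed together, 50 at each fold. With spreads drawn from the moderated variances of these arrays, limma called 16, 43, 49 and 49 of 50 probe sets changed 1.5-fold, 2-fold, 3-fold and 4-fold, and 20 unchanged probe sets beside 157 changed ones, so that 11.3% of calls were unchanged. A second simulation, made after the first was seen, drew spreads from the fitted prior and called 9, 36, 43 and 49 of 50, with 10 unchanged probe sets beside 137 changed ones, or 6.80% of calls. Both shares lie above the nominal 5%, but each comes from 1 simulated data set, which cannot show that the expected share does. Raising 20 genes of the segment 1.5-fold gave 16 and 19 calls of 20 in the simulations when adjusted over the list alone, and 0 of 20 in both when adjusted over all probe sets. Camera found the 1 list raised 1.2-fold and called 0 of 32 unchanged lists in both, with genes simulated as independent. The correlation estimated from the real arrays ran from -0.06 for red blood cell genes to 0.82 for the myelin list. The 0 of 32 therefore does not carry over to lists whose genes move together. Splits of the 6 arrays other than the real one called 6 to 17 lists at the preset correlation. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 in Python 3.11.15.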

Results

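Gene expression in the hippocampus was measured on 6 Affymetrix mouse arrays, 1 array per mouse. The duplication group held 3 mice of genotype Dp(11)17/+, which carry an extra copy of a segment of chromosome 11, and the wild-type group held 3 mice of genotype +/+. The series title names the line as a model of Potocki-Lupski syndrome, a human developmental disorder caused by duplication of the matching segment of chromosome 17. All 6 mice were labelled male, 11 to 14 weeks old and of the C57BL/6-Tyr c-Brd background. Each array gave a value for 45037 probe sets other than controls, with array medians between 3.74 and 3.79 on the log2 scale. Between 23.9% and 24.9% of the probe sets of an array lay at a log2 value of 6 or more. With 3 mice in each group, the number of arrays limits the precision of every value. Duplication and wild-type mice carried numbers that do not overlap, so litter or cohort could not be separated from genotype.

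The 6 arrays did not separate by genotype over the whole of the measured genes. Correlations across probe sets lay between 0.984 and 0.992 within the duplication group, between 0.988 and 0.991 within the wild-type group, and between 0.981 and 0.994 across groups, with probe sets that are not independent replicates. In duplication replicate 1, Xist, the RNA expressed from the inactive X chromosome of females, had a log2 value of 9.13, against 3.06 to 3.69 in the other 5 mice. The Y-linked genes Eif2s3y and Kdm5d had log2 values of 2.48 and 2.47 in that mouse, against 5.41 to 6.01 and 4.70 to 5.06 in the others. Marker genes of brain regions next to the hippocampus also differed between mice. In duplication replicate 3, the mean over 15 striatal marker genes was 1.81 above the wild-type mean on the log2 scale and that over 23 markers of thalamus and habenula was 1.76 above it. The means over markers of CA1 pyramidal cells and of dentate granule cells lay at -1.65 and -1.19 from the wild-type means in that mouse. Duplication replicate 1 had a striatal mean 1.06 above that of wild type, a thalamic mean 0.02 above it, and CA1 and dentate means at -0.45 and -0.47. Duplication replicate 2 had values of -0.14 for striatum, -0.17 for thalamus, 0.21 for CA1 and 0.53 for dentate. As a sign of RNA quality, the difference between 3' and 5' control probe sets of actin was 1.74, 1.69 and 1.47 on the log2 scale in duplication replicates 3, 1 and 2, and 1.45 to 1.63 in wild-type mice. For GAPDH it was 0.44, 0.47 and 0.33, and 0.37 to 0.57 in wild-type mice.

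**Figure D1:**
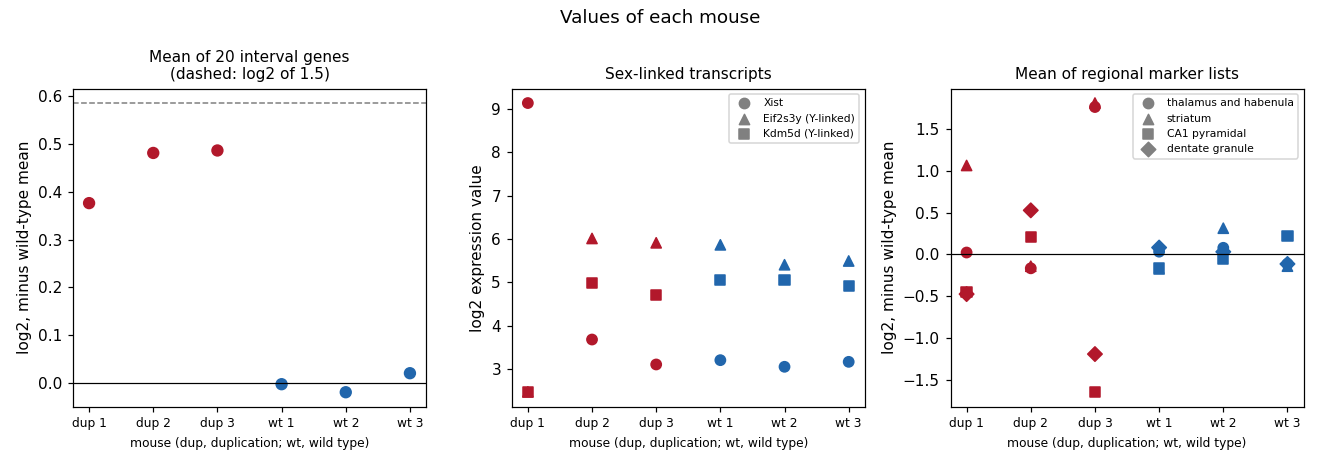
Log2 values by mouse, 3 duplication and 3 wild-type mice, as the mean of 20 genes of the duplicated segment minus the wild-type mean, as the values of Xist, Eif2s3y and Kdm5d, and as the means of 4 regional marker lists minus the wild-type mean. The mean of the segment lay 0.38 to 0.49 above wild type in the duplication mice, Xist reached 9.13 in duplication replicate 1, and the thalamic list lay 1.76 above wild type in duplication replicate 3.

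The first comparison asked whether the extra copy of the segment goes with higher expression of its genes. Most genes of the segment were higher in the duplication mice. Of the 20 genes with a mean log2 value of 6 or more, 19 were higher, with a median log2 fold change of 0.48, or 1.39-fold, and an interquartile range of 0.36 to 0.56. The mean over these 20 genes was 7.86 ± 0.06 (SD, n = 3) in duplication mice and 7.41 ± 0.02 (SD, n = 3) in wild-type mice, a difference of 0.45, or 1.36-fold. Each duplication mouse lay above all wild-type mice, by 0.38, 0.48 and 0.49 over the wild-type mean for duplication replicates 1, 2 and 3. An exact two-sided permutation test over the 20 labelings of the 6 mice gave p = 0.1, the smallest p that 3 mice against 3 can give. As a set, the 33 measured genes between Cops3 and Rnf112 were higher than other genes by camera, which was not planned for this set (p = 7.60e-27, and p = 0.00178 with an estimated correlation).

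Of the 33 genes, 29 were higher and 4 lower, and 17 were past the limma test when adjusted over the list alone, all 17 of them higher. Adjusted over all 45037 probe sets, limma called 0 of the 33 genes, with a smallest adjusted p of 0.994, while 18 had an unadjusted p under 0.05; the plain equal-variance statistic also called 0 over all probe sets. The genes are therefore named here by the adjustment over the list alone. In 17 of the 20 genes above the floor, every duplication mouse lay above every wild-type mouse, which chance gives for 5% of genes in that direction and 10% in either direction. The 95% confidence interval held the log2 value of 1.5-fold, 0.58, for 17 of the 20 genes, lay below it for 3 (Cops3, Map2k3 and Tmem11, named after their values were seen) and above it for 0. Among the 17, the intervals of Rasd1, named after its value was seen, and Rnf112 were wide enough to hold 0 as well. The mean over the 20 genes lay below 0.58 in each duplication mouse, at 0.38 to 0.49 over the wild-type mean. These 20 include the genes at the ends of the segment, Cops3 at -0.17 and Rnf112 at 0.23. How much of a true ratio the array values register was not tested, so the cause of the lower mean is not known. Among the 13 genes below the floor, 10 were higher, with a median log2 fold change of 0.12, and 1 passed, Smcr8. Leaving out 1 mouse at a time, 12 of the 17 genes passed in each of the 6 fits and all 17 stayed higher. With duplication replicate 2 as the only duplication mouse, the median log2 fold change of the genes above the floor was 0.48.

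The largest log2 fold changes were those of Alkbh5, which encodes an RNA demethylase, at 0.76 (SE 0.10, adjusted p over the list alone = 0.00336), and Llgl1, a cell polarity gene, at 0.71 (SE 0.13, adjusted p = 0.00417). Natd1 followed at 0.66 (SE 0.12), and Srebf1, a transcription factor of fatty acid and sterol synthesis, at 0.63 (SE 0.09, adjusted p = 0.00336). The log2 values of Srebf1 were 7.80 ± 0.12 in duplication and 7.17 ± 0.04 in wild-type mice (SD, n = 3). Atpaf2, an assembly factor of the ATP synthase, rose by 0.52 (SE 0.09), Nt5m, a mitochondrial nucleotidase, by 0.40 (SE 0.08), Mief2, a mitochondrial fission factor, by 0.46 (SE 0.13), and Tmem11, a protein of the inner membrane, by 0.35 (SE 0.10). Drg2, a GTP-binding protein, rose by 0.57 (SE 0.11), Med9, a subunit of the Mediator complex, by 0.55 (SE 0.12), Smcr8, a regulator of autophagy, by 0.54 (SE 0.11), and Dhrs7b by 0.52 (SE 0.09). Flii, an actin remodelling gene, rose by 0.52 (SE 0.14), Gid4, a subunit of a ubiquitin ligase, by 0.49 (SE 0.09), Tom1l2, a gene of endosomal trafficking, by 0.40 (SE 0.09), and Usp22, a deubiquitinase, by 0.37 (SE 0.11). A dimmer probe set of Tom1l2 and one of Flii gave log2 fold changes of -0.10 and -0.01. The call of Flii was lost without wild-type replicate 1 (adjusted p over the list alone = 0.0603, range 0.0182 to 0.0603 over the 6 mice). That of Mief2 was lost without duplication replicates 1 and 3 and wild-type replicates 1 and 2 (0.0573, 0.0535, 0.0610 and 0.0557, range 0.0129 to 0.0610), that of Tmem11 without duplication replicates 1 and 3 and wild-type replicate 1 (0.0573, 0.0535 and 0.0603, range 0.0129 to 0.0603). That of Usp22 was lost without duplication replicates 1 and 2 and wild-type replicates 1 and 2 (0.0987, 0.0632, 0.0776 and 0.0557, range 0.0226 to 0.0987).

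Rai1, a nuclear regulator of transcription whose loss causes Smith-Magenis syndrome in humans, rose by 0.39 on the log2 scale (SE 0.11, 1.31-fold, adjusted p over the list alone = 0.0223). Its log2 values were 7.23 ± 0.21 in duplication and 6.84 ± 0.04 in wild-type mice (SD, n = 3), and its dimmer probe set gave 0.27. Each duplication mouse lay above each wild-type mouse for Rai1. The call was lost without duplication replicate 1 or 2 or wild-type replicate 1 or 2 (adjusted p over the list alone = 0.0843, 0.0634, 0.0669 and 0.0557, range 0.0135 to 0.0843), while the log2 fold change stayed between 0.32 and 0.51. The genes at the ends of the segment did not pass. Cops3, a subunit of the COP9 signalosome, had a log2 fold change of -0.17 (SE 0.08, adjusted p over the list alone = 0.133), with all 3 duplication mice below all 3 wild-type mice. Rnf112, a brain-expressed RING finger gene, had a log2 fold change of 0.23 (SE 0.22, adjusted p over the list alone = 0.441), between 0.08 without duplication replicate 2 and 0.44 without duplication replicate 1, and its second probe set gave 0.43. It was 0.09 without wild-type replicate 2 and 0.38 without wild-type replicate 3. Map2k3 had a log2 fold change of 0.25 (adjusted p over the list alone = 0.0822).

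**Figure D2:**
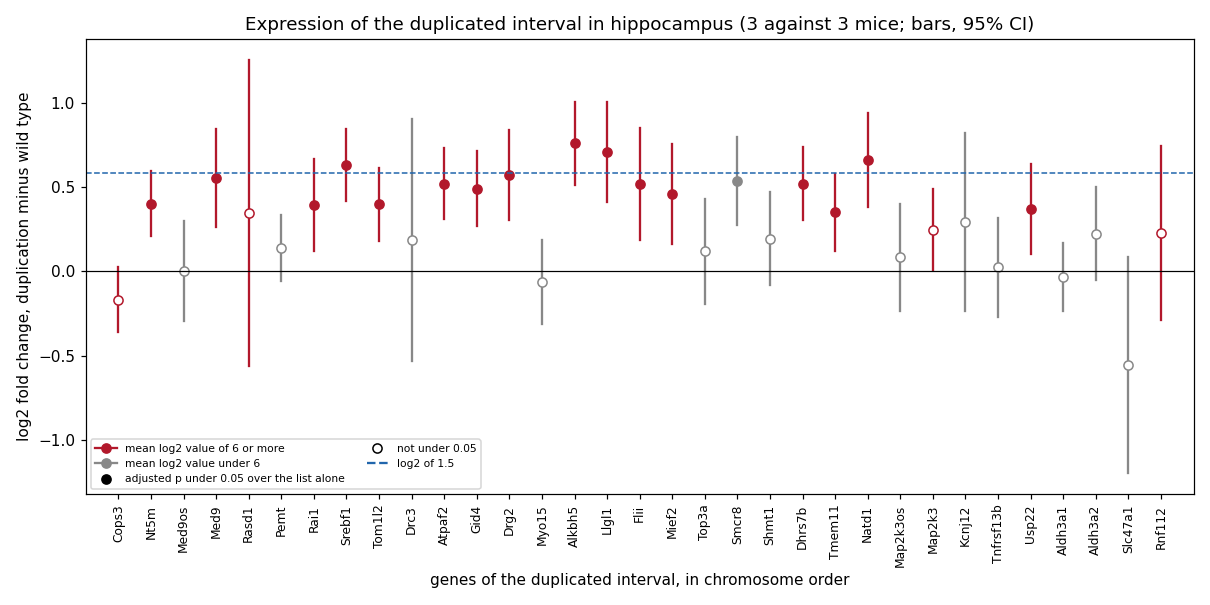
Log2 fold change, duplication against wild type, with 95% confidence interval for the 33 measured genes of the segment in chromosome order, with 20 genes at a mean log2 value of 6 or more in red and 13 dimmer genes in grey. Filled points are the 17 genes past an adjusted p of 0.05 over the list alone, and the dashed line marks 1.5-fold, or 0.58.

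The flanking genes were compared to ask whether genes next to the segment differ as well. Of 31 measured genes in the lists of neighbours, 11 were higher, 6 of 14 on the centromeric side and 5 of 17 on the telomeric side, with a median log2 fold change of -0.04. Mrpl55, a gene of the mitochondrial ribosome, fell by 0.53 on the log2 scale (SE 0.08), from 7.30 ± 0.08 in wild-type to 6.77 ± 0.04 in duplication mice (SD, n = 3). It was the 1 gene past the test adjusted over the list alone (adjusted p = 0.00889), and every duplication mouse lay below every wild-type mouse. Flcn, the folliculin gene, had a log2 fold change of 0.05 (SE 0.11), whose sign turned in some alternative fits, without duplication replicate 3 (-0.04) and without wild-type replicate 3 (-0.00) among them. Mprip, a myosin phosphatase partner, had a log2 fold change of 0.02 (SE 0.07). Adjusted over all probe sets, limma called 0 of the 31 genes, as did the plain equal-variance statistic, and 4 had an unadjusted p under 0.05. These 4 were Mrpl55, Fam83g at -0.26, Pigl at -0.26 and Wnt9a, a secreted signalling gene, at 0.91 (SE 0.22, adjusted p over the list alone = 0.0625), whose dimmer probe set gave the opposite sign, -0.09. Wnt9a passed over the list alone without duplication replicate 1 (adjusted p = 0.0477), and with all mice under an intensity trend and robust prior (0.0378). This takes the count to 2 in each of these fits. Camera and fry were not planned for the flanking genes as a set. By camera, the set gave p = 0.234, and p = 0.395 with an estimated correlation. By fry, which does not compare a set with other genes, p was 0.119 for a change in 1 direction and 0.000996 for changes in either direction.

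Across all genes, the comparison asked whether expression differs beyond the segment. Limma called 0 of the 45037 probe sets. The smallest adjusted p was 0.0578 and the next 0.994. An unadjusted p under 0.05 was given by 1272 probe sets, 647 higher and 625 lower, or 2.82% where chance gives 5%, and the plain equal-variance statistic called 0 with 1553 at an unadjusted p under 0.05. Without duplication replicate 2 the count at an unadjusted p under 0.05 was 2765, and without wild-type replicate 1 it was 2620. Outside the segment, 1243 probe sets had an unadjusted p under 0.05, and 14 of them differed at least 2-fold. In simulated data with the spread of these arrays, 200 independent probe sets with a mean log2 value of 6 or more were changed together. Limma then called 43 of 50 changed 2-fold and 16 of 50 changed 1.5-fold, or 36 and 9 of 50 in a second simulation. With only 20 genes of the segment raised 1.5-fold, it called 0 of 20 over all probe sets in both. The larger shares therefore do not carry over to few changed probe sets, and changes of dim probe sets were not simulated. None of the genes that follow passed over all probe sets in the fit of all 6 mice.

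The smallest p outside the segment belonged to Xaf1, an apoptosis gene of the interferon response on chromosome 11, at its dimmer probe set with a log2 fold change of 1.54 (SE 0.10, adjusted p = 0.0578). This probe set passed in the fit with an intensity trend and robust prior (adjusted p = 0.0338) and with array weights (0.0330). The brighter probe set of Xaf1 gave the opposite sign, -0.45, so the probe sets of this gene disagreed. Ranked next by unadjusted p were Mrpl55 and 2610507I01Rik on chromosome 11, the latter at -0.78 (SE 0.13). Lyz1, a lysozyme gene, had a log2 fold change of -0.41 at its brightest probe set and of 0.03 at another, so its probe sets disagreed too. Ddr2, a collagen receptor, had a log2 fold change of -0.53 (SE 0.10), Parm1 of -0.69 (SE 0.13), Prg4, the lubricin gene, of -0.68 (SE 0.13), and Zfp39 of -0.64 (SE 0.13). Cdhr1, a cadherin of photoreceptors and olfactory bulb, had a log2 fold change of -1.18 (SE 0.24), and its log2 value was 4.65 ± 0.46 in duplication and 5.83 ± 0.25 in wild-type mice (SD, n = 3). Ccdc173 had a log2 fold change of 0.39 at the probe set that ranked it and of -0.21 at another, so its probe sets disagreed. Its brightest probe set gave 0.06, which turned to -0.05 without duplication replicate 3 and to -0.04 without wild-type replicate 3.

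Gene groups fixed beforehand were compared to ask which pathways and cell types differ between the genotypes. Of 33 lists, 15 passed camera with a preset correlation, 10 higher and 5 lower. With the correlation estimated from the 6 arrays 0 of the 33 passed, and 0 passed fry. In each of the 33 lists, 0 members passed limma adjusted over the list alone and 0 adjusted over all probe sets, so members are given by value. The 15 lists passed with each of the 3 other scalings of the arrays and kept their direction there. The lists of sterol and fatty acid synthesis, astrocytes, oligodendrocyte precursors, endothelial cells with pericytes, and striatum passed in the same direction with each of the 6 mice left out. This was at the preset correlation, the only one run with mice left out, at which other splits of the 6 arrays called 6 to 17 lists. The 6 fits share most of their mice, so passing in each is no independent evidence for a list. With duplication replicate 2 as the only duplication mouse, 11 of the 15 kept their direction. That mouse was not free of regional differences. Its dentate mean lay 0.53 above wild type, and its regional score of -2.68 lay below every wild-type mouse.

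Striatal markers were higher in the duplication group, 15 of 15 with a median log2 fold change of 0.91 (adjusted p = 2.43e-11, and adjusted p = 0.381 with an estimated correlation). Among them were Sh3rf2 at 0.36, the transcription factor Foxp1 at 0.84 and Syndig1l at 0.98. Markers of thalamus and habenula were higher in 20 of 23, with a median of 0.30 (adjusted p = 0.000318, and 0.619 with an estimated correlation), and with Tcf7l2 at 1.29, Plekhg1 at 0.80 and the nicotinic receptor gene Chrnb4 at -0.18. CA1 pyramidal markers were lower in 12 of 12, with a median of -0.42 (adjusted p = 0.00544, and 0.616 with an estimated correlation). Fibcd1 had a log2 fold change of -1.08, the mineralocorticoid receptor gene Nr3c2 of -1.06, and Dcn, which also stands in the list of meninges, of -0.69. These lists moved with single mice. Duplication replicate 3 had log2 values of 9.19 for Prkcd and 7.01 for Tcf7l2, against 5.20 to 5.92 and 3.08 to 3.88 in the other 5 mice, and it had the highest actin difference, 1.74. The striatal median was 0.43 without duplication replicate 3 and 1.44 without duplication replicate 2, with 15 of 15 markers higher in both. Without duplication replicate 3, the thalamic list gave a median of -0.00 in the opposite direction (adjusted p = 0.775, range 1.10e-06 to 0.775 over the 6 mice) and the CA1 list one of -0.13 (adjusted p = 0.906, range 2.15e-07 to 0.906). The thalamic median was 0.73 without duplication replicate 2 and 0.60 without wild-type replicate 2, and the CA1 median was -0.82 without duplication replicate 1 and -0.75 without duplication replicate 2. With duplication replicate 2 alone against wild type, the CA1 median was 0.43, in the opposite direction, the striatal median -0.06 and the thalamic median -0.07.

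Markers of glia and vessels were higher in the duplication group. Endothelial and pericyte markers were higher in 18 of 21, with a median log2 fold change of 0.22 (adjusted p = 1.33e-09, and 0.381 with an estimated correlation), with the efflux transporter gene Abcb1a at 0.41, the angiopoietin receptor gene Tek at 0.25 and the glucose transporter gene Slc2a1 at 0.63. Astrocyte markers were higher in 18 of 20, with a median of 0.17 (adjusted p = 3.04e-07, and 0.256 with an estimated correlation). They held the gap junction gene Gjb6 at 0.34, Fgfr3 at 0.28 and the glutamate transporter gene Slc1a3 at 0.31. Oligodendrocyte precursor markers were higher in 11 of 12, with a median of 0.18 (adjusted p = 0.000103, and 0.312 with an estimated correlation), with Gpr17 at 0.30, Vcan at 0.57 and Cspg4 at 0.22, and the median was 0.12 without duplication replicate 1. Probe sets of Vcan disagreed, the lowest at -0.05. Myelin and oligodendrocyte markers were higher in 19 of 21, with a median of 0.20 (adjusted p = 8.11e-06, and 0.616 with an estimated correlation), with the transcription factors Olig1 at 0.26 and Olig2 at 0.25, and Mobp at 0.30. The myelin call was lost without duplication replicate 3 (median 0.06, adjusted p = 0.0979, range 2.97e-11 to 0.0979 over the 6 mice), the mouse with the high thalamic and striatal markers. The myelin median was 0.34 without duplication replicate 1, 0.31 without wild-type replicate 1 and 0.10 without wild-type replicate 2. Microglial markers were higher in 19 of 24, with a median of 0.09 (adjusted p = 0.00167, and 0.619 with an estimated correlation), with P2ry12 at 0.35, Csf1r at 0.24 and the lysozyme gene Lyz2 at -0.44. The microglial median was 0.17 without duplication replicate 3 and 0.15 without wild-type replicate 2. The microglial call was lost without wild-type replicate 3 (median 0.04, adjusted p = 0.154), and without duplication replicate 1, the mouse with the Xist signal, the direction turned with a median of -0.02 (adjusted p = 0.977, range 1.46e-07 to 0.977). With duplication replicate 2 alone, the astrocyte, precursor and myelin lists had medians of 0.08, 0.15 and 0.15, the endothelial list 0.14 and the microglial list 0.03.

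Genes of sterol and fatty acid synthesis, targets of the transcription factor encoded by Srebf1 among them, were higher in 27 of 33, with a median log2 fold change of 0.11 (adjusted p = 3.21e-05, and 0.397 with an estimated correlation). The desaturase gene Scd1 had a log2 fold change of 0.46, the acyltransferase gene Gpam 0.16 and Fads1 0.15. The median was 0.07 without duplication replicate 3 and 0.07 without wild-type replicate 3. With duplication replicate 2 alone against wild type, 17 of 33 were higher with a median of 0.00. Genes of the glucocorticoid response were higher in 12 of 17, with a median of 0.21 (adjusted p = 0.00129, and 0.381 with an estimated correlation), with Sult1a1 at 0.48, Tsc22d3 at 0.64, of which a dimmer probe set gave -0.17, and Errfi1 at -0.44. The glucocorticoid call was lost without wild-type replicate 2 (median 0.14, adjusted p = 0.0530, range 1.06e-06 to 0.0530 over the 6 mice), and the median was 0.12 without duplication replicate 2. Autism-associated genes were higher in 15 of 22, with a median of 0.05 (adjusted p = 0.0451, and 0.429 with an estimated correlation), with Foxp1, also a striatal marker, at 0.84, Shank3 at 0.28 and Avpr1a at -0.14. The autism call was lost without duplication replicate 1 or 3 (adjusted p = 0.359 and 0.138) and without wild-type replicate 1 or 3 (0.336 and 0.0934), over a range of 0.00494 to 0.359. The autism median was 0.08 and 0.12 without duplication replicate 2 and wild-type replicate 2, and 0.03 without duplication replicate 3 or wild-type replicate 1. Its direction turned with duplication replicate 2 alone, with 8 of 22 higher and a median of -0.02.

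Of the 5 lists that were lower, 4 were groups other than CA1 markers. Heat shock and protein folding genes were lower in 21 of 23, with a median log2 fold change of -0.11 (adjusted p = 0.00544, and 0.381 with an estimated correlation), with the chaperone genes Chordc1 at -0.25, Dnaja1 at -0.19 and Ahsa1 at -0.17. This call was lost without duplication replicate 2 (adjusted p = 0.122) and without wild-type replicate 2 (0.0530), over a range of 0.000711 to 0.122, and the median was -0.17 without wild-type replicate 1. Subunits of the COP9 signalosome other than Cops3 were lower in 8 of 9, with a median of -0.14 (adjusted p = 0.0101, and 0.381 with an estimated correlation), with Gps1 at -0.17, Cops8 at -0.18 and Cops6 at -0.14. The COP9 call was lost without duplication replicate 2 (adjusted p = 0.0615) and without wild-type replicate 2 (0.124), over a range of 0.00788 to 0.124. Markers of meninges and fibroblasts were lower in 15 of 19, with a median of -0.15 (adjusted p = 0.00548, and 0.312 with an estimated correlation), with the growth factor gene Igf2 at -0.38, Aldh1a2 at -0.65 and Slc6a13 at -0.55. The call of the meninges was lost without duplication replicate 1 (adjusted p = 0.0620) and without wild-type replicate 1 (0.0751), over a range of 0.000307 to 0.0751, and the median was -0.07 without duplication replicate 1 and -0.25 without duplication replicate 2. Interferon response genes were lower in 16 of 21, with a median of -0.09 (adjusted p = 0.0451, and 0.619 with an estimated correlation), with Rsad2 at -0.21, Usp18 at -0.27 and Ifi27 at -0.52. The interferon call was lost without duplication replicate 1 or 2 (adjusted p = 0.120 and 0.240) and without wild-type replicate 1 (0.834), over a range of 0.00225 to 0.834. The interferon median was -0.00 without wild-type replicate 1, -0.13 without duplication replicate 3 or wild-type replicate 3 and -0.15 without wild-type replicate 2. With duplication replicate 2 alone, the heat shock and interferon lists had medians of -0.12 and -0.08, and the COP9 and meninges lists of -0.12 and -0.12.

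**Figure D3:**
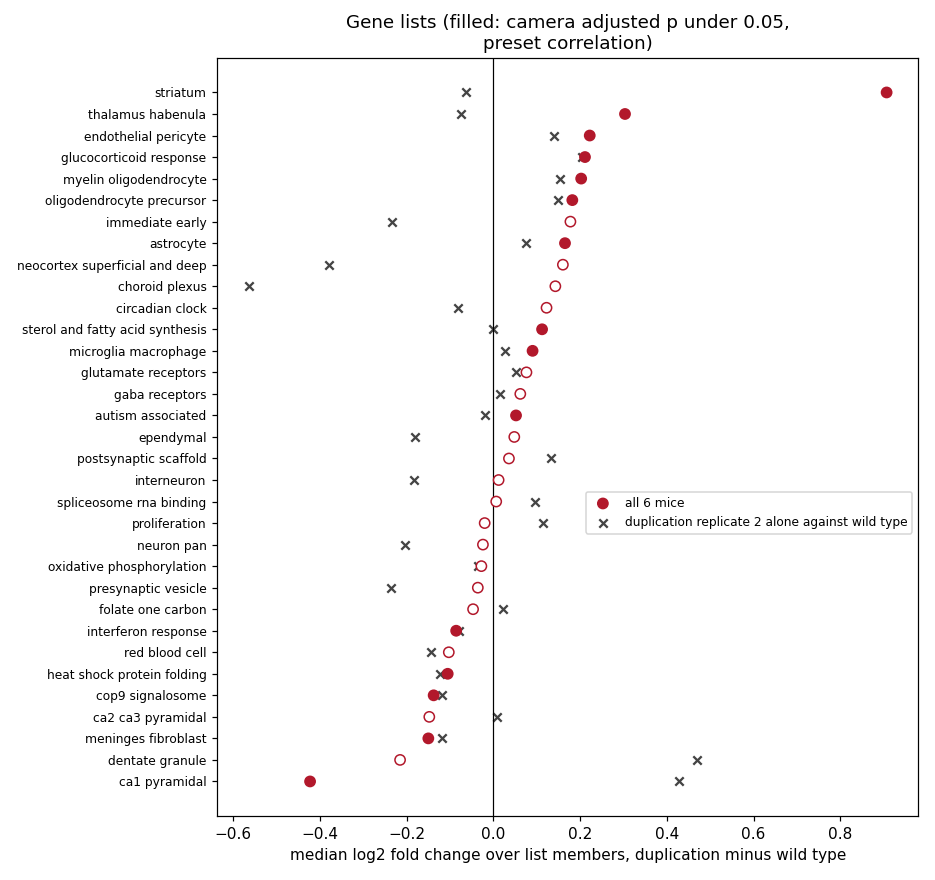
Median log2 fold change, duplication against wild type, of the members of 33 gene lists, with filled points for the 15 lists past an adjusted p of 0.05 by camera with a preset correlation. Crosses give the same median with duplication replicate 2 as the only duplication mouse, which for CA1 markers is 0.43 against -0.42 with all 3 duplication mice.

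The rest of chromosome 11 was compared with other chromosomes to ask whether differences cluster on the rearranged chromosome. No gene passed an adjusted p, so an unadjusted p under 0.01 was used, a threshold chosen after the values were seen, as were the genes named by it. Outside the segment, 14 genes of chromosome 11 lay under it, 13 lower and 1 higher. The lower genes were Gpr75 at -0.41, the interferon-induced Ifi47 at -0.41, Zfp39, 2610507I01Rik, Mrpl55, the lipoxygenase genes Alox12b at -0.43 and Alox8 at -0.38, Xaf1 by its brighter probe set, Cyb5d2 at -0.34, Bhlha9 at -0.40, the Golgi transport genes Gosr1 at -0.33 and Copz2 at -0.46, and Klhl10 at -0.30. Wnt9a was the higher gene. Probe sets disagreed in sign for Wnt9a and Xaf1, and for Cyb5d2 and Gosr1, whose dimmer probe sets gave 0.03 and 0.04. Of the 14, Mrpl55 and Gosr1 had a mean log2 value of 6 or more. Apart from the flanking lists, 12 of 1379 genes on chromosome 11 and 54 of 16578 elsewhere had p under 0.01, 0.870% against 0.326%, an odds ratio of 2.69 (95% confidence interval 1.30 to 5.10, two-sided Fisher exact p = 0.00407). At p under 0.001 the counts were 1 and 0 (Fisher exact p = 0.0768), and at p under 0.05 they were 49 and 503, an odds ratio of 1.18 (Fisher exact p = 0.291). The odds ratio at p under 0.01 fell to 1.28 without duplication replicate 1, 1.15 without duplication replicate 2, 1.94 without wild-type replicate 3 and 0.73 without wild-type replicate 1, and to 0.61 with genes of a mean log2 value under 6 left out. In other fits of all 6 mice it was 2.01 with an intensity trend and robust prior (Fisher exact p = 0.0988), 1.62 with array weights (p = 0.166), 1.33 with the plain equal-variance statistic (p = 0.322) and 1.24 with the regional score as a covariate (p = 0.634), so the difference did not hold at p under 0.05 in these 4 fits. The count of 14 was 7 without duplication replicate 1, 37 without duplication replicate 2, 9 without duplication replicate 3, 9 without wild-type replicate 2, 6 without wild-type replicate 3, 9 with the trend and robust prior and 7 with the covariate. As a set, the 1379 genes gave a camera p of 0.433, in a test that was not planned.

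**Figure D4:**
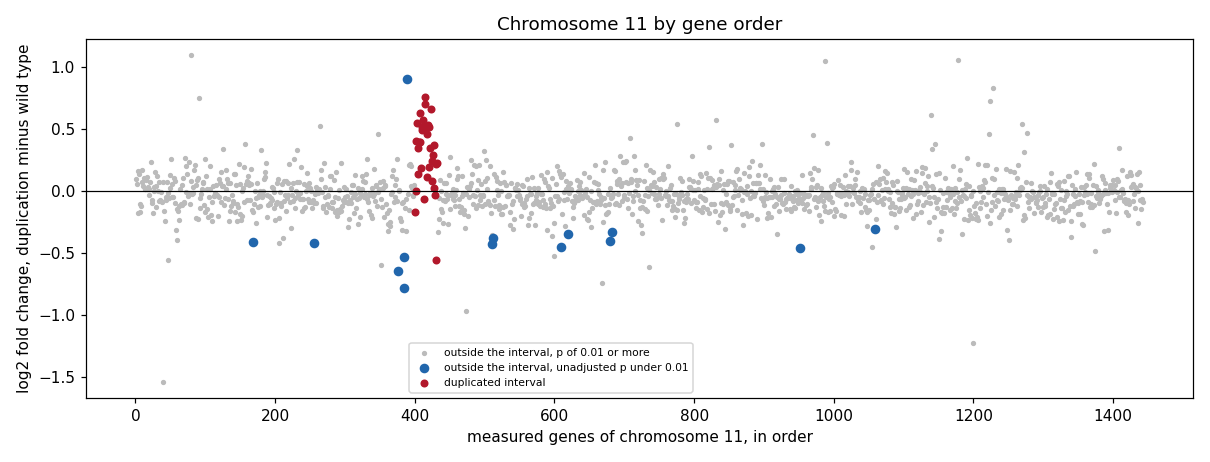
Log2 fold change, duplication against wild type, of 1443 measured genes of chromosome 11 in their order along the chromosome, with the segment at positions 400 to 432 of that order. Blue points are the 14 genes outside the segment with an unadjusted p under 0.01, of which 13 were lower.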

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

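Tests chosen only after the result was seen were those of a swap, of mixed RNA, of other brain regions, of genotype acting alike, of sex and RNA degradation for the regional markers, of the share of lower genes, with and without Xaf1, and of distance on chromosome 11, with and without the flanking genes, the count of splits for probe sets past an adjusted p, and the fits with duplication replicate 2 alone and with the regional score as a covariate.

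Xist stood at a log2 value of 9.13 in duplication replicate 1, a mouse labelled male, a signal outside the comparisons of the report. A swap of a duplication with a wild-type mouse was argued against by the segment's mean in this mouse, 0.376 above a wild-type mean whose SD was 0.0199. Female RNA mixed into a male sample was argued against by Eif2s3y, at percentile 2.37 of that array. A female animal is a candidate explanation, since 4 genes that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) had a median of 0.378 above the mean of the other 5 mice. Whether the animal or the label differs was not tested, and sex remains an open difference within the duplication group.

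In the group means, striatal and thalamic marker lists passed as higher and CA1 markers as lower, none of them with an estimated correlation (adjusted p = 0.381, 0.619 and 0.616), while dentate markers did not pass (median -0.21, adjusted p = 0.280, and 0.06 without duplication replicate 3). Genotype acting alike in all duplication mice was argued against, since 2 of 3 had a regional score above every wild-type mouse and duplication replicate 2, at -2.68, lay below all of them (-2.33 to -1.95). Sex was argued against for duplication replicate 3, whose Xist value of 3.11 lay within the wild-type range of 3.06 to 3.21. In the 2 other mice with a GAPDH difference between 3' and 5' probe sets as high, the thalamic mean lay at most 0.0329 above the wild-type mean, against 1.76 in duplication replicate 3. This does not settle RNA degradation for the thalamic markers, since no other mouse had as high an actin difference. Also, 1 of the 2 mice was wild-type replicate 1, itself part of the wild-type mean. The other, duplication replicate 1, came close in actin, at 1.69 against 1.74, with a thalamic mean 0.02 above wild type. Other brain regions in the dissected tissue of single mice stay open, since the 4 of 4 marker lists that moved that way by over 3 wild-type SD in duplication replicate 3 are those by which this mouse was chosen, and so lend no support; its abundant markers of those regions included Prkcd at 9.19, Ppp1r1b at 8.38 and Pde10a at 7.99, and wild-type hippocampus had a mean log2 value of 6 or more for 6 of 23 thalamic, 7 of 15 striatal, 12 of 12 CA1 and 8 of 16 dentate markers, of which 5, 2, 1 and 0 stand in another list. For the count of lists, 4 of the 10 splits of the 6 arrays gave as many as the real 15, the highest other being 17, and 10 splits are too few for a share under 0.05. RNA degradation stays open for the thalamic, striatal, CA1 and dentate markers, since in duplication replicate 3 only 1 of 2 differences between 3' and 5' control probe sets lay above every wild-type mouse (actin 1.74 against 1.45 to 1.63, GAPDH 0.44 against 0.37 to 0.57). Litter, sex in duplication replicate 1 and an effect of genotype that varies between mice stay open too, untested.

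On chromosome 11, 14 genes outside the segment had p under 0.01, and for the comparison of the 12 apart from the flanking lists the odds ratio was 2.69 as reported and between 0.730 and 2.54 with each mouse left out. With the regional score as a covariate the odds ratio was 1.24 (95% confidence interval 0.438 to 2.88), an interval too wide to tell apart regional make-up of the tissue from other sources. Sequence variants of another strain under the probes, which the labels' single background does not name, stay open, since 13 of all 14 genes were lower against 34 of 54 on other chromosomes (Fisher exact p = 0.0487), a p that was 0.0493 with Xaf1 left out and 0.124 with Xaf1, whose probe sets disagree, counted as higher by its dimmer probe set. An effect of the segment that falls with distance stays open as well, since the median distance of all 14, 161.5 genes against 353 over all outside genes of the chromosome, was matched by 0.99% of 10000 random draws, and by 2.05% without the flanking genes, but strain variants linked to the segment would lie near it too. Of the 10 splits, 3 gave as many as 14 genes, the real one among them, the highest other being 39. The split with 39 genes also had 4339 probe sets with an unadjusted p under 0.05, and its odds ratio was 0.868. Over the splits other than the real one the odds ratio lay between 0.515 and 1.37, against 2.69 in the real one. The 10 splits are too few for a share under 0.05.

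For the other counts the 10 splits of the arrays are likewise too few for a share under 0.05. The real split gave 17 genes of the segment past the test adjusted over the list alone, where 1 of the 10 splits, the real one, gave as many and the highest other gave 1. It gave 1 flanking gene, where 1 of the 10 gave as many and the highest other gave 0. For probe sets past an adjusted p, 10 of 10 splits gave at least the real 0, and the highest other gave 3. For 1272 probe sets with an unadjusted p under 0.05, 7 of 10 gave as many and the highest other gave 4339. That split set duplication replicates 1 and 3 and wild-type replicate 2 against the rest. It was picked as the highest of the 10 after the counts were seen, and the cause of its count was not tested.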

How the results depend on the processing

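Tests chosen only after the data were seen were duplication replicate 2 alone, the regional covariate, 30 neighbours and the thresholds on chromosome 11. Of the alternatives for counts and summary values, 146 left the value equal or close, 14 moved it, 8 weakened it and 3 reversed it. Close meant within 1.5-fold for counts and within the pooled SD of the mice (0.046) for the segment's median and mean. For the odds ratio it meant the same outcome of the Fisher exact test at p under 0.05. Counts over all probe sets were 0 in nearly every setting, so the tally is no measure of robustness. For named genes 447 kept the sign and 8 reversed it. Probe sets past an adjusted p of 0.05, 0 as reported over the array and outside the segment, were 1 with an intensity trend and robust prior and 1 with array weights, both Xaf1, and 1 over the array at an adjusted p of 0.1. Genes of the segment past the test over the list alone numbered 17 as reported, 12 to 18 with each mouse left out, where fewer mice were compared, 13 to 17 in other planned settings with 1 value per gene, 23 with every probe set counted, 12 and 18 at adjusted p of 0.01 and 0.1, and 15 with the covariate. The median of the segment was 0.455 to 0.491 with each mouse left out, 0.478 with duplication replicate 2 alone, 0.503 with the covariate, 0.350 without a floor and 0.398 with a floor of 8, and the difference in means per mouse was 0.428 to 0.483. Flanking genes past the test over the list alone were 2 with trend and robust prior, 1 to 2 with each mouse left out and 3 with 30 neighbours on each side. Lists past the test were 0 with an estimated correlation, 0 by fry, 13 to 17 in other settings and 11 to 21 with each mouse left out. The odds ratio of chromosome 11 was 0.730 to 2.54 with each mouse left out and 2.50 to 2.79 with the 3 other scalings of the arrays. It was 0.606 with probe sets of mean 6 or more, 1.47 with the brighter probe sets and 2.01 with trend and robust prior. With array weights it was 1.62, with the plain statistic 1.33, with duplication replicate 2 alone 0.828 and with the covariate 1.24. Ccdc173, at 0.06, reversed to -0.0667 with array weights, -0.00957 with the covariate, -0.0529 without duplication replicate 3 and -0.0435 without wild-type replicate 3 (range -0.0529 to 0.214 with each mouse left out). Flcn, at 0.05, reversed to -0.00617, -0.0361, -0.0437 and -0.00379 in the same order (range -0.0437 to 0.129). Except where fewer mice were compared, the cause was not tested. No paired analysis was possible because the labels give the groups no shared replicate numbers. Flanks and windows by coordinates, and a covariate from the sample titles, which do not part the arrays, were not run. Dim probe sets limit what can be seen, since under 25% of values lay at a log2 value of 6 or more.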

Other observations

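Of the gene lists fixed beforehand, 18 did not pass camera with a preset correlation (adjusted p of 0.0596 to 0.846), and their members are given by value. The fits with duplication replicate 2 as the only duplication mouse were chosen after the data were seen. Among synaptic groups, 12 of 21 glutamate receptor genes were higher, with a median log2 fold change of 0.08 (adjusted p = 0.0596), with Gria3 at 0.29, Grin2b at 0.28 and Grik3 at 0.52. This list passed with quantile normalization again (adjusted p = 0.0496) and with arrays centred on their medians (0.0468), and the circadian list with the centring (0.0468). Postsynaptic scaffold genes were higher in 14 of 22, with a median of 0.04 (adjusted p = 0.0768), with Shank3 at 0.28, Homer3 at -0.54 and Dlgap3 at 0.32. GABA receptor genes were higher in 9 of 13 (median 0.06, mean -0.04, test direction higher, adjusted p = 0.423), with Gabra5 at -0.92, Gabra2 at -0.89 and Gabrb1 at -0.19. Presynaptic vesicle genes were higher in 11 of 24 (median -0.04, against a test direction of higher, adjusted p = 0.621), with Unc13a at 0.28, Syn2 at -0.38 and Rims1 at 0.35. Immediate early genes of neuronal activity were higher in 20 of 30 (median 0.18, adjusted p = 0.0851), with Fosl2 at -0.52, Nptx2 at 0.48 and Nr4a3 at -0.84, and circadian clock genes in 15 of 21 (median 0.12, adjusted p = 0.0654), with Dbp at 0.77, Arntl at -0.36 and Rorb at 0.89. Of 12 genes shared by neurons, 5 were higher (median -0.02, adjusted p = 0.846), with Nefl at -0.13, Stmn2 at -0.15 and Snap25 at -0.08. Leaving out duplication replicate 2 brought calls of higher for circadian (adjusted p = 0.00169), immediate early (0.00126), glutamate receptor (0.0391) and presynaptic genes (0.00383). Leaving out wild-type replicate 1 did so for circadian (0.00113) and immediate early genes (3.32e-06), wild-type replicate 2 for glutamate receptors (0.0159), and duplication replicate 3 or wild-type replicate 3 for scaffold genes (0.00766 and 0.0343). The list of neurons was called lower without duplication replicate 3 (0.00377). All these calls are from camera at the preset correlation. An estimated correlation, with which 0 of 33 lists passed on all 6 mice, was not run with mice left out. Over the 6 mice left out, adjusted p spanned 0.00113 to 0.936 for circadian, 3.32e-06 to 0.977 for immediate early, 0.0159 to 0.359 for glutamate receptor, 0.00766 to 0.374 for scaffold, 0.00383 to 0.886 for presynaptic and 0.00377 to 0.977 for neuronal genes. Medians spanned -0.02 to 0.16 for circadian (lowest without duplication replicate 3), -0.01 to 0.41 for immediate early (lowest without wild-type replicate 3, highest without wild-type replicate 1), 0.02 to 0.14 for glutamate receptor, 0.02 to 0.14 for GABA receptor, -0.02 to 0.09 for scaffold, -0.07 to 0.03 for presynaptic and -0.14 to 0.06 for neuronal genes. When duplication replicate 2 alone was compared, the medians were -0.23 for immediate early, -0.24 for presynaptic and -0.20 for neuronal genes. The test direction of the neuronal list turned to higher with cyclic loess (adjusted p = 0.988).

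Cells of the dentate gyrus, the other hippocampal fields and neighbouring tissue were also compared. Dentate granule cell markers were higher in 3 of 16 (median -0.21, adjusted p = 0.280), with Trpc6 at -0.54, Plk5 at -0.38 and Pdzd2 at 0.81, whose probe sets disagreed. CA2 and CA3 markers were higher in 7 of 17 (median -0.15, adjusted p = 0.675), with Cpne4 at -0.57, Pcp4 at 0.64 and Grik4 at -0.49, and interneuron markers in 13 of 25 (median 0.01, adjusted p = 0.516), with Htr3a at -0.33, Npy at 0.51 and Tac1 at 0.91. Neocortical markers were higher in 13 of 21 (median 0.16, adjusted p = 0.283), with Fezf2 at -0.79, Tle4 at -0.16 and Crym at -0.98. Choroid plexus markers were higher in 15 of 21 (median 0.14, adjusted p = 0.376), with Igf2 at -0.38, Ttr at 1.76 and Tmem72 at 0.14. Ttr, the transthyretin gene, had log2 values of 12.99 and 12.96 in duplication replicates 1 and 3 and 13.07 in wild-type replicate 1, against 8.54 to 10.84 in the others. Ependymal markers were higher in 8 of 15 (median 0.05, adjusted p = 0.236), with Rarres2 at 0.26, Tmem212 at 0.50 and Tekt1 at -0.18, and red blood cell genes in 3 of 8 (median -0.10, adjusted p = 0.272), with Alas2 at -0.40, Hbb-bh1 at -0.21 and Epb42 at -0.16. Without duplication replicate 2, dentate markers were called lower (adjusted p = 2.15e-07) and interneuron (0.00679), neocortical (0.000238), choroid plexus (0.00671) and ependymal markers (0.00494) higher. Choroid plexus (7.09e-10) and ependymal markers (0.00455) were also called higher without wild-type replicate 1, and interneuron markers (0.0158) without wild-type replicate 2. These calls are from camera at the preset correlation. An estimated correlation, with which 0 of 33 lists passed on all 6 mice, was not run with mice left out. Over the 6 mice left out, adjusted p spanned 2.15e-07 to 0.689 for dentate, 0.00679 to 0.911 for interneuron, 0.000238 to 0.977 for neocortical, 7.09e-10 to 0.986 for choroid plexus and 0.00455 to 0.956 for ependymal markers. The choroid plexus median spanned -0.27 without wild-type replicate 2 to 0.86 without wild-type replicate 1 and was also below 0 without duplication replicate 1 or 3 or wild-type replicate 3 (-0.01, -0.13 and -0.18). The dentate median spanned -0.57 without duplication replicate 2 to 0.06 without duplication replicate 3, and the neocortical median 0.00 without duplication replicate 3 to 0.50 without duplication replicate 2. Medians spanned -0.09 to 0.14 for interneuron, -0.08 to 0.21 for ependymal, and -0.19 to -0.01 for CA2 and CA3 markers. Compared with wild type by duplication replicate 2 alone, the median was 0.47 for dentate, -0.18 for interneuron, -0.38 for neocortical, -0.56 for choroid plexus and -0.18 for ependymal markers. These signs were the opposite of the calls without that mouse.

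Among general cell functions, oxidative phosphorylation genes were higher in 13 of 35 (median -0.03, adjusted p = 0.460), with Sdhd at -0.16, Sdhb at -0.09 and Atp5o at -0.10. Genes of folate and 1-carbon metabolism were higher in 7 of 18 (median -0.05, mean 0.01, test direction higher, adjusted p = 0.376), with Atic at -0.21, Folh1 at 0.18 and Aldh1l1 at 0.25. Proliferation genes were higher in 11 of 24 (median -0.02, mean 0.00, test direction higher, adjusted p = 0.376), with Ccna2 at 0.39, Cenpa at -0.27 and Rrm2 at 0.31. Spliceosome genes were higher in 12 of 24 (median 0.01, mean -0.02, test direction higher, adjusted p = 0.621), with Hnrnpc at -0.30, Hnrnpm at -0.23 and Srsf2 at 0.12. At the preset correlation, the only one run with mice left out, oxidative phosphorylation was called lower without duplication replicate 3 (adjusted p = 0.00766, range 0.00766 to 0.886 over the 6 mice), and folate genes higher without wild-type replicate 1 (0.0415, range 0.0415 to 0.673). Medians spanned -0.08 to 0.01 for oxidative phosphorylation, -0.05 to 0.03 for folate, -0.04 to 0.04 for proliferation and -0.04 to 0.03 for spliceosome genes, whose median was -0.00 with arrays centred on their medians. In the comparison of duplication replicate 2 alone, the medians were 0.11 for proliferation and 0.10 for spliceosome genes.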
